A study of Mus musculus with 4 samples.

How the data were processed

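Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on ventricles of wild-type C57BL/6 mouse hearts at postnatal day 6. Each precipitation used the pooled ventricles of 10 hearts. The antibodies were against TCF7L2, a DNA-binding factor of the TCF/LEF family that acts in Wnt signalling, against GATA4, a zinc-finger transcription factor of heart development, and against H3K27ac, histone H3 acetylated at lysine 27, a mark of active promoters and enhancers. An input sample belongs to the series as the background control, and no list of it was used here.

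The authors deposited 1 peak list per antibody, 3 lists in all, and every list holds a chromosome, a start and an end for each peak and no other column. The deposited values are therefore positions in bp, without a height, fold or significance for any peak. Per the submitters' processing notes, the tools were FastQC 0.10.0, Bowtie2 2.2.6.2, MACS2 2.1.1.20160309.0 and deepTools, and the genome build was mm9. Per the labels, there were 2 biological replicates for each antibody. How these were combined into 1 list, the peak threshold and any excluded regions are not given in the sources used here. The spacing of the lists gives some properties of the calling. The smallest gap between neighbouring peaks was 52 bp in the TCF7L2 list, 51 bp in the GATA4 list and 501 bp in the H3K27ac list. The most common GATA4 width was 125 bp, shared by 1676 peaks. Only 39 peaks in the 3 lists were narrower, and all 39 had a border at a multiple of 100 bp, as did 1.56% to 2.97% of the other peaks of each list.

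Positions are given 1-based in mm9. The gene table at hand is for GRCm38.p6, another build, so no peak was assigned to a gene, and the planned tests of promoters, gene lists and sequence motifs were not run. Regions are named by position, by a fixed rule: the 10 widest TCF7L2 peaks, the 10 widest of those on both GATA4 and H3K27ac, the 10 widest GATA4 peaks, the 5 longest H3K27ac peaks and stretches, and the 5 windows of 100 kb with the most TCF7L2 peaks. Width stands in for peak strength because the lists hold no score. This rule, the 10 tests reported and the other settings listed first below, with the exceptions named there, were chosen before the data were examined; settings and tests given as added were chosen afterwards.

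Peaks that share 1 bp or more were counted as overlapping. Overlap was tested with 1000 rotations: all peaks of a list were moved together along each chromosome by a random offset between the first and last position seen in the 3 lists, which keeps widths and spacing. This one-sided permutation test cannot give a p below 0.001. TCF7L2 and GATA4 were compared with Fisher's exact test. Joint occurrence inside H3K27ac peaks was tested with the Cochran-Mantel-Haenszel chi-square test over 10 strata of H3K27ac width. Median widths were compared with 100000 permutations, two-sided, for which the smallest p is 1e-05. H3K27ac stretches are H3K27ac peaks joined across gaps of up to 12.5 kb, and the longest 5% were called long. Shares carry 95% Wilson intervals, which cover counting error over peaks only. Benjamini-Hochberg adjustment was made over the 10 tests. Two-sided Fisher's exact tests compared X with the autosomes, and Zelen's exact test compared the odds ratios of the factors. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.

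The procedures were tested on simulated data, with fewer rotations and permutations per test than were used for the real lists. With 60% of 774 simulated peaks placed inside the real H3K27ac peaks, the overlap counted was 59.9%. This share was set by the placement, so it checks the counting of overlaps and not the recovery of an unknown share. The rotation test made a call in 20 of 20 of these simulations, against 1 of 20 with no effect. These calls do not show whether rotated positions are a suitable expectation for the real lists. A planted common odds ratio of 4 over 75011 H3K27ac peaks was recovered as 4.05, with a call in 4 of 200 simulations when the planted ratio was 1. The simulated rates were constant within each width stratum, so effects of width left inside a stratum were not tested. A planted difference of 30 bp in median width was recovered as 29.8 bp, with a call in 197 of 200 simulations and in 10 of 200 with no difference.

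With 1 list per antibody there is no replicate error: p-values refer to peak positions within these lists, and neighbouring peaks are not fully independent. Read depth is unknown, since the lists give no counts. A place with high background in chromatin could be called in several lists, and the input, which would show this, was not analysed here. The other settings run were other overlap rules, 200 bp windows around the midpoint, autosomes only, uniform redraws, no width strata, H3K27ac peaks joined across 1 kb, width-weighted draws, only factor peaks in H3K27ac, and other stretch definitions. Exceptions are the 200 bp windows for the widths of shared peaks and the autosomes for long stretches, which were added. Other added ones were local shifts, the widths of factor peaks inside and outside H3K27ac, the graded shifts and the positions within H3K27ac peaks given in the results, 50 width strata, H3K27ac peaks of the median width or wider, random GATA4 subsets of the size of the TCF7L2 list, leaving out directly overlapping pairs, and leaving out a cluster of TCF7L2 peaks on chromosome 8. Alternatives that needed a peak score could not be run.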

Results

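The 3 peak lists describe where TCF7L2, GATA4 and H3K27ac were enriched in the chromatin of mouse ventricles at postnatal day 6. The TCF7L2 list held 774 peaks with a median width of 198.5 bp, covering 180.2 kb. The GATA4 list was longer, with 10530 peaks of median width 184 bp covering 2.32 Mb. Acetylation was called over 75011 peaks of median width 1287 bp, which together covered 248.6 Mb, or 9.65% of the 2577 Mb between the first and last positions on each chromosome. Each antibody had 1 list, so no value below has a replicate error.

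The first comparison asked in which chromatin TCF7L2 lay. Most TCF7L2 peaks were in acetylated chromatin: 645 of 774 overlapped an H3K27ac peak, 83.3% (95% Wilson interval 80.5 to 85.8). Rotated positions gave 11.2% ± 1.30 (SD over 1000 rotations), so the observed share was 7.44-fold higher and lay above every rotation (permutation p = 0.001, the smallest this test can give, adjusted p = 0.00125). Against shifts of 20 to 100 kb, added after the data were seen, the expected share was 26.3% and the excess 3.16-fold. The remaining 129 TCF7L2 peaks, 16.7%, lay outside H3K27ac, and only 14 of these were within 1 kb of an H3K27ac peak. All of the 10 widest TCF7L2 peaks lay in H3K27ac. The widest, on chromosome 11 from 98448537 to 98449691, spanned 1155 bp inside an H3K27ac peak of 10.1 kb. Next came a peak of 812 bp on chromosome 1 from 74634100 to 74634911 in an H3K27ac peak of 7.97 kb, and one of 809 bp on chromosome 6 from 48551564 to 48552372 in an H3K27ac peak of 6.25 kb. The fourth was a peak of 788 bp on chromosome 11 from 108781632 to 108782419, and a peak of 731 bp on chromosome 2 from 30639805 to 30640535 sat in an H3K27ac peak of 23.2 kb.

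GATA4 was likewise found mainly in acetylated chromatin. Of 10530 GATA4 peaks, 8358 overlapped H3K27ac, 79.4% (78.6 to 80.1), against 11.1% ± 0.529 (SD) at rotated positions, a 7.15-fold difference (permutation p = 0.001, adjusted p = 0.00125). The same shifts of 20 to 100 kb gave 27.02% and a 2.94-fold excess. The other 2172 GATA4 peaks, 20.6%, lay outside H3K27ac and had a median width of 153 bp against 195 bp inside (permutation p = 1e-05, the smallest possible; a test added after the data were seen). Of the widest GATA4 peaks most lay outside: 8 of the 10 widest had no H3K27ac and none of the 10 overlapped TCF7L2. The widest of all spanned 2132 bp on chromosome 10 from 86930353 to 86932484. It was followed by a peak of 1950 bp on chromosome 2 from 127128411 to 127130360 and one of 1818 bp on chromosome 5 from 15882301 to 15884118, all 3 without H3K27ac. The widest GATA4 peak with acetylation, of 1493 bp on chromosome 7 from 51727401 to 51728893, lay in an H3K27ac peak of 13.2 kb.

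TCF7L2 lay in H3K27ac slightly more often than GATA4 did. The odds ratio was 1.30 (95% interval 1.07 to 1.58; Fisher's exact test, two-sided, p = 0.00832, adjusted p = 0.00925). The shares differed by little, 83.3% against 79.4%. On autosomes alone the odds ratio was 1.23 (1.01 to 1.50; Fisher's exact p = 0.0404). The test treats the lists as independent, although 314 TCF7L2 peaks overlapped 315 GATA4 peaks, so its p-values are approximate. The call depended on the setting in alternatives added after the data were seen. With only H3K27ac peaks of the median width or wider the odds ratio was 1.18 (0.991 to 1.42; Fisher's exact p = 0.0668), and with random GATA4 subsets as small as the TCF7L2 list it was 1.29 (0.9995 to 1.67; Fisher's exact p = 0.0581, medians over 200 subsets for the ratio and p), so that neither passed. Without the chromosome 8 cluster it was 1.41 (1.15 to 1.72; Fisher's exact p = 0.000773).

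**Figure D1:**
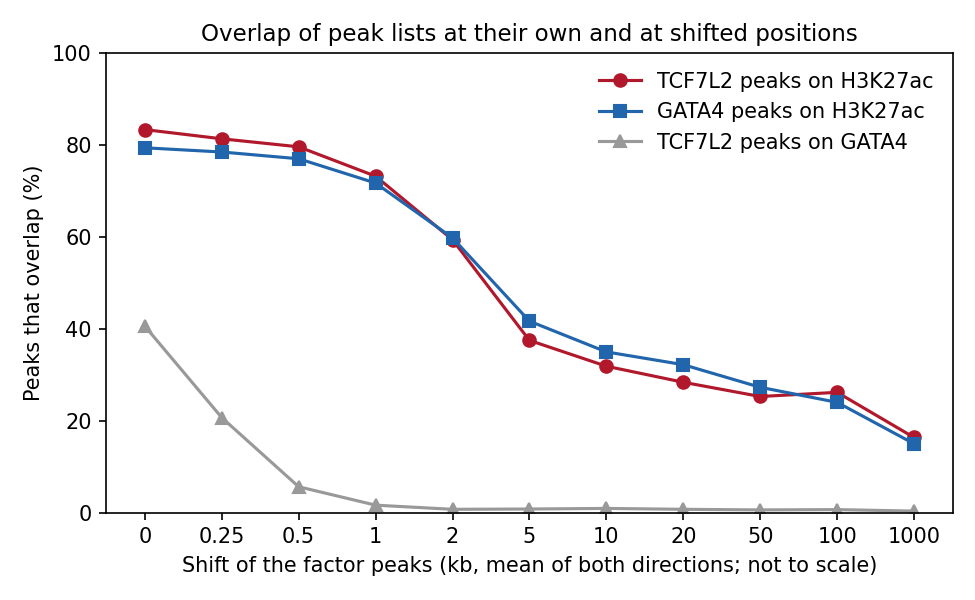
Share of peaks (%, y axis) that overlapped the other list at their own position (shift 0) and after a shift of up to 1000 kb (x axis, mean of both directions); red circles are TCF7L2 on H3K27ac, blue squares GATA4 on H3K27ac and grey triangles TCF7L2 on GATA4. The overlap with H3K27ac fell over several kb, from 83.3% to 37.5% for TCF7L2 at 5 kb, while that of TCF7L2 with GATA4 fell from 40.6% to 5.62% within 0.5 kb.

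The speed at which overlap is lost with a shift depends on the width of the intervals shifted against, and GATA4 peaks are far narrower than H3K27ac peaks. After a shift of 1 kb, 73.2% of TCF7L2 and 71.7% of GATA4 positions still fell on H3K27ac, and at 100 kb the shares were 26.2% and 24.0%, above the rotated values. Of TCF7L2 positions, 1.61% were on a GATA4 peak after a shift of 1 kb. Inside H3K27ac peaks of 2 kb or more, both factors lay nearer the centre than random positions would, in a test added after the data were seen. On a scale from 0 at the centre to 1 at the border, 579 TCF7L2 peaks had a mean of 0.425 ± 0.261 (SD) and 7587 GATA4 peaks a mean of 0.393 ± 0.253 (SD). Uniform positions have a mean of 0.5 (permutation of positions, p = 0.0001 for each, the smallest possible).

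The next comparison asked whether TCF7L2 and GATA4 occupied the same places. A large minority of TCF7L2 peaks, 314 of 774 or 40.6% (37.2 to 44.1), overlapped a GATA4 peak. Rotated positions gave 0.191% ± 0.164 (SD) and at most 0.904%, so the overlap was 212-fold higher (permutation p = 0.001, adjusted p = 0.00125). Shifts of 20 to 100 kb, which stay in the same neighbourhood, gave 0.466% and an 87.1-fold excess. Only 26.3% of TCF7L2 positions so shifted fell on H3K27ac, so this excess does not allow for both factors lying mainly in H3K27ac. The share was 31.5% and the excess 378-fold when 50% of the TCF7L2 peak had to be covered, and 46.1% and 45.9-fold when peaks within 1 kb counted. With random GATA4 subsets as small as the TCF7L2 list, added after the data were seen, the share had a median of 2.97% over 200 subsets, and the subset of middle rank gave a 190-fold excess (permutation p = 0.001). Seen from GATA4 the shared places were few, 315 of 10530 peaks or 2.99% (2.68 to 3.33). The midpoints of overlapping peaks were a median of 45 bp apart (quartiles 17.3 and 109 bp). Overlap of such narrow peaks itself keeps midpoints close, and no expected distance was computed. For the 460 TCF7L2 peaks without GATA4 overlap the nearest GATA4 midpoint was a median of 37.2 kb away.

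Shared peaks were wider than the others in both lists. TCF7L2 peaks with GATA4 had a median width of 211.5 bp against 186.5 bp without (permutation p = 0.000540, adjusted p = 0.00108). For GATA4 peaks with and without TCF7L2 the medians were 236 and 183 bp (permutation p = 1e-05, the smallest possible, adjusted p = 2.5e-05). Wide peaks overlap more often by chance, and the differences were 23 and 50 bp when overlap was taken from windows of 200 bp, a setting added after the data were seen. Among the 10 widest TCF7L2 peaks, 5 carried GATA4. The peak on chromosome 11 from 98448537 to 98449691 overlapped 3 GATA4 peaks, and 1 each was found under those on chromosome 10 (126748747 to 126749484), chromosome 17 (34740535 to 34741253), chromosome 11 (86921999 to 86922710) and chromosome 14 (61664853 to 61665558). The next widest with GATA4 and H3K27ac were on chromosome 5 (139874259 to 139874917, in an H3K27ac peak of 56.2 kb), chromosome 19 (4793817 to 4794429 and 6141027 to 6141610), chromosome 17 (56601502 to 56602082) and the X chromosome (98727814 to 98728391).

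By combination, 253 TCF7L2 peaks (32.7%, 29.5 to 36.1) had both GATA4 and H3K27ac, 392 (50.6%, 47.1 to 54.2) had H3K27ac without GATA4, 61 (7.88%, 6.18 to 9.99) had GATA4 without H3K27ac, and 68 (8.79%, 6.99 to 10.99) had neither. Of the 392 acetylated TCF7L2 peaks without GATA4, 111 (28.3%, 24.1 to 33.0) shared their H3K27ac peak with a GATA4 peak elsewhere in it.

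Acetylated peaks that held TCF7L2 also tended to hold GATA4. TCF7L2 was present in 616 of 75011 H3K27ac peaks, and 343 of these (55.7%, 51.7 to 59.6) held GATA4, against 8.28% (8.09 to 8.48) of H3K27ac peaks without TCF7L2. Allowing for H3K27ac width, the common odds ratio was 4.73 (3.96 to 5.64; Cochran-Mantel-Haenszel chi-square test, p = 1.75e-81, adjusted p = 1.75e-80). It was 13.9 (11.8 to 16.3) without width strata, and 2.84 (2.02 to 3.99) with random GATA4 subsets as small as the TCF7L2 list, the latter added after the data were seen. Without the TCF7L2 and GATA4 peaks that overlapped each other directly, an alternative chosen after the data were seen, it was 1.24 (0.963 to 1.59; chi-square test, p = 0.104). That alternative removes joint occurrences by construction, so its odds ratio describes only pairs lying apart within an H3K27ac peak.

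**Figure D2:**
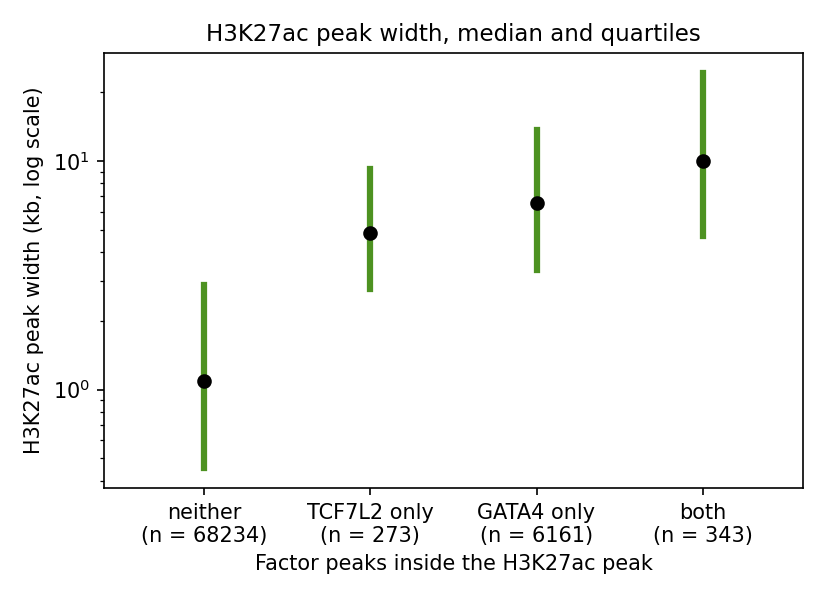
Width of H3K27ac peaks (kb, log scale, y axis) that hold neither factor, TCF7L2 only, GATA4 only or both (x axis, with the number of peaks); dots are medians and bars run from the lower to the upper quartile. Medians were 1088 bp with neither, 4861 bp with TCF7L2 only, 6565 bp with GATA4 only and 10044 bp with both.

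Broad acetylated peaks held the factors more often than narrow ones. H3K27ac peaks with TCF7L2 had a median width of 6878.5 bp against 1267 bp without, a difference of 2.44 on the log2 scale (permutation p = 1e-05, adjusted p = 2.5e-05). With and without GATA4 the medians were 6682.5 and 1095 bp, a log2 difference of 2.61 (permutation p = 1e-05, adjusted p = 2.5e-05). A broad peak offers more places to overlap. Drawn in proportion to width, as many peaks would have had a median of 7923 bp for TCF7L2, so that its peaks were 0.868 times as wide as the draws (log2 difference -0.20, permutation p = 0.0195), a reversed direction. For GATA4 the draws had a median of 5876 bp, and the observed peaks were 1.14 times as wide (log2 difference 0.19, permutation p = 0.0001, the smallest possible). Both sets of draws came from the same H3K27ac list, with 616 peaks drawn for TCF7L2 and 6504 for GATA4. The median of the draws was nevertheless lower for GATA4. A peak hit more than once counted once, and surplus peaks were removed at random. The median therefore depended on this procedure and on how many peaks were drawn. The GATA4 excess over its draws therefore cannot show that these peaks were wider than their width alone would give. For the same reason the opposite directions of the factors cannot be compared, and their difference was not tested.

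All of the 5 longest H3K27ac peaks held GATA4, and those on chromosomes 1 and 8 also held TCF7L2. The lists differ in length, with 10530 GATA4 and 774 TCF7L2 peaks, and no test was made on these H3K27ac peaks. The longest H3K27ac peak, 241.3 kb on chromosome 11 from 88163687 to 88404980, held 5 GATA4 peaks and 0 TCF7L2 peaks. The second, 227.6 kb on chromosome 14 from 26269833 to 26497461, held 7 and 0, and the third, 225.0 kb on chromosome 1 from 73948132 to 74173104, held 19 GATA4 peaks and 1 TCF7L2 peak. An H3K27ac peak of 179.8 kb on chromosome 8 (11243230 to 11423013) held 8 and 1, and one of 172.1 kb on chromosome 7 (119343320 to 119515382) held 12 and 0. Joining H3K27ac peaks across gaps gave 20708 stretches, of which the 1036 longest were 90.0 kb or more. These were stretches ranked by length, without any measure of signal. TCF7L2 lay in a long stretch in 221 of 662 cases (33.4%, 29.9 to 37.1) and GATA4 in 3172 of 8527 (37.2%, 36.2 to 38.2), an odds ratio of 0.846 (0.716 to 1.0002) that did not pass the threshold (Fisher's exact test, two-sided, p = 0.0544, adjusted p = 0.0544). It did so when gaps of up to 3 kb were joined (0.784, Fisher's exact p = 0.00613) or when the longest 10% were taken (0.810, Fisher's exact p = 0.00974). GATA4 was present in 887 of the 1036 long stretches and TCF7L2 in 185, with both in 170. These long stretches made up 40.3% of the length of all stretches, more than the share of either factor's peaks in them. Neither factor was therefore concentrated in long stretches relative to their length, which was not tested. The longest stretch, 664.1 kb on chromosome 13 from 11644175 to 12308232, joined 118 H3K27ac peaks and held 10 GATA4 peaks and 0 TCF7L2 peaks. The next were on chromosome 6 (72129126 to 72741391, 612.3 kb, 11 GATA4 and 0 TCF7L2 peaks), chromosome 8 (122511532 to 123123368, 611.8 kb, 13 and 1), chromosome 11 (87842284 to 88408892, 566.6 kb, 16 and 1) and chromosome 2 (165604710 to 166132392, 527.7 kb, 9 and 0).

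TCF7L2 peaks came together in few places, with 3 or more in only 6 windows of 100 kb. The window on chromosome 8 from 57900001 to 58000000 held 10 TCF7L2 peaks and 5 GATA4 peaks, and none of the TCF7L2 peaks overlapped H3K27ac. Windows on chromosome 11 (95600001 to 95700000 and 108700001 to 108800000), chromosome 19 (7000001 to 7100000) and chromosome 5 (122500001 to 122600000) held 3 TCF7L2 peaks each, all of them in H3K27ac.

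**Figure D3:**
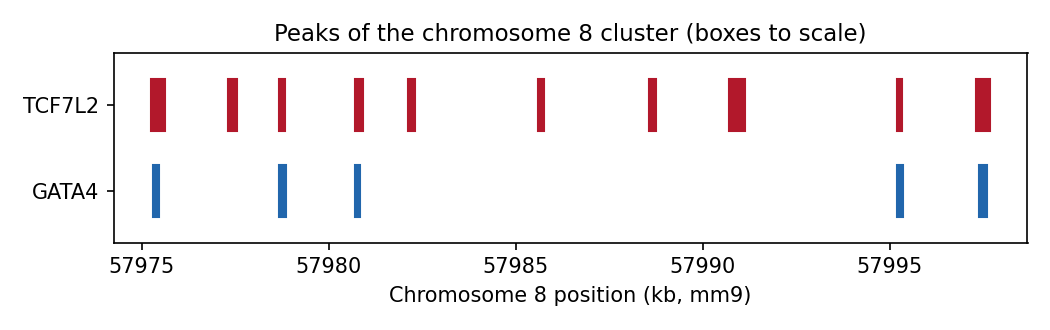
Positions of TCF7L2 peaks (red boxes) and GATA4 peaks (blue boxes) in the chromosome 8 window, with mm9 position in kb on the x axis and 1 line per list; boxes are drawn to scale. The 10 TCF7L2 peaks lay between 57975251 and 57997682, and 5 of them overlapped 5 GATA4 peaks.

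Among the autosomes, H3K27ac covered from 7.28% of chromosome 3 to 17.0% of chromosome 11, and chromosome 11 also had the most TCF7L2 peaks per Mb (0.556) and the most acetylated GATA4 peaks per Mb (6.28). The X chromosome was lower than every autosome in H3K27ac coverage (1.68%), in TCF7L2 peaks per Mb (0.116) and in acetylated GATA4 peaks per Mb (0.386).

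**Figure D4:**
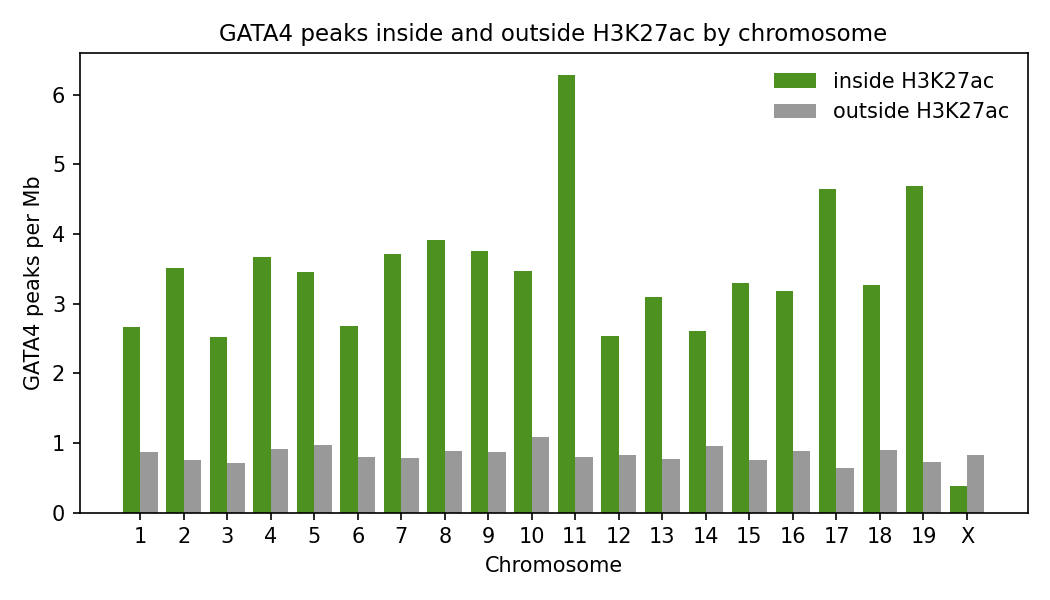
GATA4 peaks per Mb (y axis) inside H3K27ac (green bars) and outside it (grey bars) on each autosome and X (x axis). Peaks inside ranged from 2.52 to 6.28 per Mb on autosomes and were 0.386 on X, while those outside ranged from 0.640 to 1.09 on autosomes and were 0.820 on X.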

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

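The X chromosome comparison and its explanations were tested only after the values were seen, and the measure for H3K27ac on X was changed from a fold to an odds ratio because a share cannot pass 100%. The factors differed in how X compared with the autosomes. Of GATA4 peaks, 63 of 197 on X overlapped H3K27ac, 32.0% (25.9 to 38.8), against 8295 of 10319 on autosomes, 80.4% (79.6 to 81.1), an odds ratio of 0.115 (Fisher's exact test, two-sided, p = 7.51e-48). For TCF7L2 the counts were 15 of 19 on X, 78.9% (56.7 to 91.5), and 630 of 755 on autosomes, 83.4%, an odds ratio of 0.744 (Fisher's exact p = 0.540). The ratio of the odds ratios was 6.49 (Zelen's exact test, p = 0.000785), with only 19 TCF7L2 peaks on X behind it.

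GATA4 peaks outside H3K27ac on X had a density of 0.820 per Mb (exact Poisson interval 0.687 to 0.971), within the autosomal range of 0.640 to 1.09. This argues against extra peaks there only if X was called at the same rate as the autosomes. Fewer copies of X would lower every call, yet that density was 0.999 times the autosomal median. The ratio covers only GATA4 peaks outside H3K27ac, which may include places of high background. All other classes lay below the lowest autosome: 0.116 against 0.172 per Mb for TCF7L2, 7.84 against 23.5 for H3K27ac and 0.386 against 2.52 for acetylated GATA4 peaks. Fewer copies therefore stay open as a part of the pattern, and with them extra GATA4 peaks outside H3K27ac. Less H3K27ac on X stays open: the odds of overlap over those at rotated positions were 25.4 (18.8 to 34.2) on X and 32.1 (30.6 to 33.7) on autosomes, while as a fold over rotated positions X was higher, 17.6 against 7.11. The measures differ in direction, so they may bound the role of coverage only loosely. Why H3K27ac was called over only 1.68% of X was not tested, and no biological explanation was tested.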

How the results depend on the processing

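Of 51 alternatives, 33 planned and 18 added after the data were seen, 45 kept direction and side of the threshold. The odds ratio of TCF7L2 over GATA4 for lying in H3K27ac no longer passed with H3K27ac peaks of the median width or wider (1.18, Fisher's exact p = 0.0668) or with random GATA4 subsets as small as the TCF7L2 list (1.29, Fisher's exact p = 0.0581), the latter with fewer peaks by construction; both were added. Joint occurrence in H3K27ac peaks fell to an odds ratio of 1.24 without directly overlapping pairs, also added, which removes joint occurrences by construction. Against width-weighted draws, the width difference of H3K27ac peaks with TCF7L2 reversed to -0.20 on the log2 scale. The odds ratio for long stretches passed the threshold with gaps of up to 3 kb (0.784) and with the longest 10% (0.810); the cause was not tested. Local shifts raised the expected H3K27ac overlap to 26.3% for TCF7L2 and 27.02% for GATA4, so the excess was 3.16-fold and 2.94-fold. Intended settings that needed a peak score (stricter lists, GATA4 ranked down to the TCF7L2 length, another score column) and those for promoters, gene lists and motifs were not run. No paired analysis was possible because each antibody had 1 list. Depth is unknown, so the shorter TCF7L2 list cannot be put down to binding or to depth.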

Other observations

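The tests in this part were chosen after the results were seen, except the comparison of interval shapes and the 200 bp windows; the latter were first meant to test peak width, and the widths themselves were compared in their place because the windows alter peaks inside and outside H3K27ac differently. GATA4 peaks outside H3K27ac varied less in density between chromosomes than those inside; the difference itself was not tested. Over the autosomes and X, counts outside varied by 1.48 times the Poisson variance (chi-square test, p = 0.0827), against 52.1 times inside (chi-square test, p = 8.66e-198). Without X the values were 1.55 and 28.8 times. Such a ratio grows with the number of peaks, and the whole list held 2172 GATA4 peaks outside and 8358 inside. The ratios outside and inside are therefore not on one scale. Per Mb, autosomes ranged from 0.640 to 1.09 outside and from 2.52 to 6.28 inside.

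Sharing between the factors was also present outside H3K27ac. GATA4 overlapped 61 of 129 TCF7L2 peaks outside H3K27ac, 47.3% (38.9 to 55.9), and 253 of 645 inside, 39.2% (35.5 to 43.0), with an odds ratio of 1.39 (0.9504 to 2.03; Fisher's exact test, two-sided, p = 0.0954). It passed the threshold with 200 bp windows, at 1.52 (1.04 to 2.22; Fisher's exact p = 0.0369; 46.5% outside and 36.4% inside), and did not without the chromosome 8 cluster, at 1.38 (0.930 to 2.04; Fisher's exact p = 0.127). In the GATA4 list, TCF7L2 overlapped 2.67% of peaks outside and 3.07% inside (Fisher's exact p = 0.358).

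A position just beyond an H3K27ac border is argued against, since 9.84% of the 61 shared peaks (4.59 to 19.8) lay within 1 kb of H3K27ac. Wider peaks outside are not excluded for TCF7L2, whose median width differed by -18 bp (permutation p = 0.0662), while GATA4 peaks were narrower outside, by -42 bp (permutation p = 1e-05, the smallest possible). Places of high background that take one shape in every precipitation stay open. The Jaccard index of the paired intervals had a median of 0.810 outside and 0.497 inside, a difference of 0.314 (permutation p = 1e-05, the smallest possible). Among TCF7L2 peaks of 150 to 250 bp the difference was 0.394. GATA4 widths were not restricted, and GATA4 peaks with TCF7L2 had a median of 213 bp outside and 263 bp inside, so width is not set aside. Places of high background may account for part of the sharing, the input was not analysed here, and no biological explanation was tested.

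The cluster on chromosome 8 placed 10 TCF7L2 peaks in 22.4 kb, with the nearest H3K27ac peak 28.7 kb away. A tandemly repeated unit could produce this, and the regularity of the midpoints did not decide it (random placement, permutation p = 0.1135; the reading of this p as undecided was set after it was seen). No sequence was used here, and no biological explanation was tested.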
